A study of Drosophila melanogaster with 6 samples.

How the data were processed

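Messenger RNA of 6 samples was measured: 3 libraries of eye discs and 3 of antennal discs from last-instar Drosophila larvae of yw genotype. Per the labels' protocols, each library came from 30 discs, dissected in saline, freed from the mouth hooks and parted by hand into eye and antennal portions, and was made with a stranded Illumina mRNA kit. The labels call the 3 samples of a tissue biological replicates but do not say whether equal replicate numbers mark the same larvae or day. Groups and replicate numbers were taken from the sample titles.

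The deposited expression tables hold estimated counts and TPM (transcripts per-million) for 17753 gene identifiers, 1 row per gene, in the column layout of kallisto per the file headers. FastQC, kallisto, bedtools and the dm6 genome are named in the submitters' processing notes; their versions, the strand setting and the annotation release are not given in the sources used here. The listed length of a gene equals its whole span from first to last base, introns included, for 99.3% of the 12768 genes with more than 1 exon, and equals the longest transcript for 1.10%. Reads were thus assigned to gene spans, 47.6% of which overlap another indexed gene, and 3368 genes (19.1%) lie wholly inside the spans of others. Where spans overlap, estimated counts can be shared out between genes in either direction, and without a stated strand setting this includes genes on opposite strands. Values of such genes are therefore uncertain, and the text says where a named gene is wholly covered. TPM values were divided by these span lengths by the authors' tool, so that genes with long introns have low TPM. Symbols and coordinates came from a dm6 annotation and matched 17622 identifiers, while the other 131 stayed without a name.

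A further deposited file per sample lists genes within 39 genomic regions with their TPM, and these values equal the TPM of the expression table in all 6 samples. Gene coordinates match the annotation in 653 of its 670 region and gene pairs, with starts counted from 0. They are printed counted from 1. The files list genes at TPM 0 and carry no column that says which genes the authors took as active, so a gene was taken as active above TPM 0, with TPM 1, TPM 10 and 1 CPM as alternatives.

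Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, libraries were scaled by TMM, and eye disc was tested against antennal disc with the edgeR 4.0.16 quasi-likelihood test (robust, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over 9901 genes and calls at an adjusted p under 0.05. CPM are counts per-million of the TMM-scaled library, given as mean ± SD over 3 libraries. The SE of a log2 fold change is approximate: its absolute value divided by the square root of the F statistic of the test. The thresholds of 1 CPM, for active genes and for an alternative count filter, used libraries without TMM scaling. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 25 lists. Active genes per region were averaged per sample and compared by an exact two-sided permutation test with scipy 1.17.1, without a test across regions, which overlap. Tables of regions were made with pandas 2.3.3 and plots with matplotlib 3.10.9 in Python 3.11.15. A fold against a tissue at 0 in all libraries is given as a lower bound, with 3 counts in its library of highest floor in place of 0.

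Eye disc replicate 2 had the fewest counts, 17583649 against 25032893 to 29093995 in the others, and the smallest TMM factor, 0.891. Its top 10 genes held 12.5% of the counts, against 6.25% to 6.75% elsewhere. Replicates differed by more than sampling noise, with chi-square per degree of freedom between 16.0 and 352 for pairs of libraries of 1 tissue, so that no library was counted as a copy of another. Samples of equal number deviated together from their tissue means: the correlation across genes was 0.415, 0.308 and 0.242 for numbers 1, 2 and 3, each sample correlating best with its own number. The numbers may therefore pair the samples, a reading that rests on this check and not on the labels. The check is weak, since few matchings of 3 with 3 exist and deviations within a tissue sum to 0. The main tests, fixed beforehand, carry no block, and the fit with a block is an alternative.

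The steps were tested on a single draw of simulated counts for the 9901 genes of this comparison. In it 100 genes were changed 2-fold and 100 were changed 4-fold, up or down in equal number. The edgeR test recovered 59% of genes changed 2-fold and 78% of those changed 4-fold, with 8.67% false among 150 calls. DESeq2 1.42.0 recovered 69% and 85%, with 29.0% false among 217 calls. The blocked edgeR fit recovered 54% and 76%, with 11.6% false among 147 calls, and limma-trend on log2(TPM + 1) recovered 41% and 75%, with 6.45% false among 124 calls. Of 25 simulated lists, camera called the raised list and 0 of the unchanged ones. The simulated genes were drawn independently of each other, whereas the real lists had estimated correlations of up to 0.655. The simulation therefore cannot show how camera behaves on lists whose genes vary together. It also held no replicate effect, so it cannot show what a block gains or costs with paired samples. The false share was thus above the nominal 5% for the edgeR test in this simulation. Recovery and false share depend on how many genes change, and the real comparison called 2610 genes, far more than were changed here. These shares therefore do not carry over to the real calls.

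The tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, upper-quartile scaling, no count filter, a filter of 1 CPM in 3 samples, the DESeq2 Wald test, limma-trend on log2(TPM + 1), effective-length offsets, the replicate block, leaving out each sample, an adjusted p under 0.01, a test against a 2-fold change, a log2 fold change of at least 2, and an estimated correlation in camera. Chosen after seeing the data were fits to genes that overlap no other, counts summed over runs of overlapping genes, fits without eye disc replicates 2 and 3, and 1 CPM as a threshold of activity. The naming rule took the 12 genes with the largest called difference per direction, with at least 5 CPM and ranges that do not overlap, up to 4 called and 2 uncalled members of each list, and a set of tissue markers. Of the uncalled members it allows, 28 were left out of the text after their values were seen, the largest of their log2 differences being 2.36. eyg, bnb, bi, st, wor, Lcp65Ag1, Yp2, Egfr and vn were named after their values were seen, as were the genes named for the regions or for families of symbols.

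The lists covered retinal determination, photoreceptor fate, phototransduction, antennal fate, the Odd-skipped family, morphogens, dorsoventral patterning, Hox and head gap genes, Enhancer of split and Bearded genes, the cell cycle, ecdysone response, neurons, glia, hemocytes, fat body, muscle, trachea, salivary gland and cuticle, brain and ring gland, chemosensation, heat shock, dosage compensation, pigment, EGF receptor signalling and planar polarity. The members esg, Orc1, Nplp2 and nvd matched no symbol and were not analysed here. Transcript usage could not be analysed from 1 row per gene.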

Results

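RNA-seq profiles were collected from the eye disc and the antennal disc of Drosophila melanogaster larvae in the third instar. These joined epithelial sacs, the imaginal discs, form the adult eye, antenna and much of the head capsule. Each tissue was represented by 3 libraries of polyadenylated RNA, each from 30 discs of yw larvae, a stock mutant for yellow and white. The estimated counts summed to 25711627, 17583649 and 25032893 in eye disc replicates 1, 2 and 3, and to 27652241, 29093995 and 25720706 in antennal disc replicates 1, 2 and 3. Between 11814 and 12273 genes had an estimated count above 0 in a library. At these depths 3 counts corresponded to between 0.1 and 0.192 CPM (normalised counts per-million), a floor that covers counting error only. The first principal component of log2 CPM held 62.8% of the variance and separated the tissues, and the second held 16.6%. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.979 to 0.982 between antennal disc libraries, 0.945 to 0.963 between eye disc libraries and 0.900 to 0.932 between tissues.

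The main comparison asked which genes differ in level between eye and antennal disc. The eye determination genes eya, ey and so were higher in eye disc, and Dll and ss, which act in the antenna, were higher in antennal disc. eya (FBgn0000320, 2L, 6527447 to 6546976 in dm6) was at 494 ± 27.5 CPM (SD, n = 3) in eye disc and 42.1 ± 7.14 CPM in antennal disc. Dll (FBgn0000157, 2R, 24814822 to 24835667), the homeobox gene of distal appendages, was at 13.7 ± 6.09 CPM in eye disc and 228 ± 38.2 CPM in antennal disc. The antennal selector gene ss (spineless, FBgn0003513, 3R, 16374434 to 16403690) was at 13.4 ± 2.61 against 103 ± 10.1 CPM. Neither eya nor Dll was absent from the libraries of the other tissue. The antennal disc libraries held 35.4 to 49.6 CPM of eya, and the eye disc libraries 9.34 to 20.6 CPM of Dll. The discs were parted by hand, and whether these reads came from carried-over tissue was not tested.

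With log2 fold changes taken as eye disc over antennal disc, eya differed by 3.55 ± 0.14 (SE), ey (FBgn0005558, a PAX6 homologue) by 3.19 ± 0.17, so (FBgn0003460) by 3.11 ± 0.07, toy by 2.23 and Optix by 1.97. The photoreceptor transcription factor gl (FBgn0004618) was at 268 ± 17.6 against 12 ± 4.06 CPM, a log2 fold change of 4.48 ± 0.27. The glial transcription factor repo was at 42.8 ± 3.92 against 4.47 ± 0.972 CPM, a log2 fold change of 3.26. On the antennal side, Dll differed by -4.08 ± 0.35, ss by -2.94 ± 0.16, hth by -1.36 and ct by -1.05. The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p between 6.42e-06 for so and 0.00110 for ct. The antennal genes dan and danr were higher in eye disc, by 1.11 and 0.52 (edgeR quasi-likelihood test, adjusted p = 0.000122 and 0.00068), and the span of dan lies wholly inside that of another gene. The dosage compensation RNA roX1 was at 232 ± 37.5 against 260 ± 30.4 CPM, a difference within the replicate spread (log2 fold change -0.16, edgeR quasi-likelihood test, adjusted p = 0.423). The rhodopsin gene ninaE, at 0.17 ± 0.121 against 0.0717 ± 0.00492 CPM, was too low to test, as were y at 0 in every library and w at 0 against 1.00 ± 1.74 CPM. The spans of y and w are wholly covered by other genes.

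**Figure D1:**
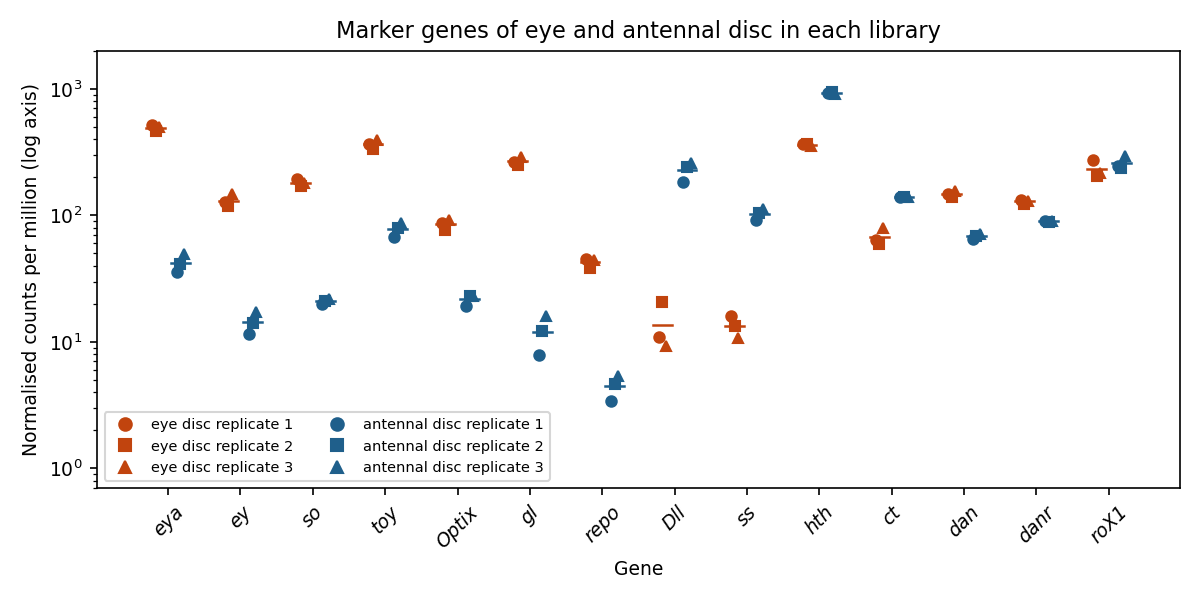
Normalised counts per-million (log axis) of 14 genes that mark eye or antennal disc, one point per library and a horizontal line at the mean of each tissue. eya, ey, so, toy, Optix, gl, repo, dan and danr lie higher in all 3 eye disc libraries, Dll, ss, hth and ct in all 3 antennal disc libraries, and roX1 overlaps between tissues.

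Of 9901 genes tested, 1449 were higher in eye disc, 1161 were higher in antennal disc and 7291 were not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The eye disc held most of the large differences: 913 genes were higher there by at least 2-fold and 610 by at least 4-fold, against 171 and 76 in antennal disc. The replicate ranges of the tissues did not overlap for 45.6% of the tested genes, where 10% is the share that chance gives for 3 against 3, nor for any called gene. The counts fell to 919 and 596 without antennal disc replicate 2 and to 947 and 520 without antennal disc replicate 3. Eye disc genes made up 55.5% of the calls, and 71.4% under limma-trend on log2(TPM + 1), although that fit moved the median of all genes by -0.19, toward antennal disc.

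The largest differences toward eye disc were in genes whose span lies wholly inside another gene's span. The EGF receptor ligand protease ru (FBgn0003295, 3L, 1370628 to 1387437) was at 188 ± 14.6 CPM in eye disc and 0 in every antennal disc library, at least 1638-fold higher, taking 3 counts in a library as the floor. Summed with the genes it overlaps, the values were 391 ± 8.95 and 193 ± 3.11 CPM, a log2 ratio of 1.02. On the same floor orion was at least 355-fold, CG11029 288-fold, eIF4G2 281-fold, 2mit 255-fold, CG30197 104-fold and the noncoding RNA noe 66.5-fold higher in eye disc, noe at least 31.9-fold without eye disc replicate 3. Summed in the same way, their log2 ratios were 0.07 for orion, 0.39 for CG11029, 0.57 for eIF4G2, 1.01 for 2mit and 0.36 for noe. The sum of CG30197 lay toward antennal disc (-0.54, 58.0 against 84.5 CPM). Such sums also hold the other genes' own differences. VAChT, the neuronal ankyrin Ank2, the secreted EGF receptor antagonist aos and CG4822 followed, at log2 fold changes of 7.54, 6.94, 6.19 and 5.64, and all 4 are wholly covered too. VAChT had 2 counts in antennal disc, a ratio of 210 with a counting interval of 58.3 to 1738. Leaving out 1 library moved these: VAChT was at 6.52 without eye disc replicate 3 and at least 50-fold higher without antennal disc replicate 3, which held both counts, Ank2 at 8.20 without antennal disc replicate 1, and aos at 5.57 and 7.44 without antennal disc replicates 2 and 3. Some of these calls ended with 1 library left out, as fewer samples alone can do (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). eIF4G2 was at least 219-fold higher without eye disc replicate 3 (adjusted p = 0.0737), Ank2 at 6.80 without antennal disc replicate 2 (0.0605) and aos at 6.07 without antennal disc replicate 1 (0.0614). CG4822 was lost in 5 of the 6 fits that left out 1 library, all but the fit without antennal disc replicate 1, at log2 fold changes of 5.04 to 5.89 where lost and at least 169-fold higher in that fit, where antennal disc was at 0. Its call was also lost with the replicate number as a block (adjusted p = 0.0743). The twelfth, kek3, overlaps no other gene (log2 fold change 5.27, edgeR quasi-likelihood test, adjusted p = 0.000482).

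The largest differences toward antennal disc were mostly in genes free of overlap. SmD3 and CR43361, which lie wholly inside other genes, were at 0 in every eye disc library and at least 155-fold and 30.1-fold higher in antennal disc, or 259-fold and 50.2-fold on the lower floor without eye disc replicate 2. Summed with the genes they overlap, both turned toward eye disc (log2 ratio 0.12, 792 against 727 CPM, and 0.28, 322 against 264 CPM). In antennal disc SmD3 and CR43361 were only 29.8 and 5.76 CPM of these sums, which so mostly follow the other genes. CG11584, 70.1% of whose span is covered by another gene, had a log2 fold change of -5.43 and lost its call without any 1 of the antennal disc replicates, at -5.64 without replicate 1, -5.43 without replicate 2 and -5.25 without replicate 3, and was at -4.82 without eye disc replicate 3 and at least 41.3-fold higher in antennal disc without eye disc replicate 1, where eye disc was at 0. The other 9 overlapped no gene: CG34461 (-4.97), the cuticle protein gene Cpr92A (-4.80), the homeobox gene H2.0 (-4.75), the T-box gene H15 (-4.41), CG15322 (-4.35), CG8172 (-4.31), Dll and the forkhead genes fd96Ca (-4.26) and fd96Cb (-4.04). CG34461 was at -5.62 without eye disc replicate 1, and H2.0 and H15 at -6.20 and -5.32 without eye disc replicate 2. H15 was at 3.97 ± 3.51 CPM in eye disc and 81.0 ± 8.82 CPM in antennal disc, and fd96Cb at 5.43 ± 3.29 against 87.3 ± 4.07 CPM. Among genes that overlap no other, a set looked at after the values were seen, the largest differences toward eye disc were in kek3, the phototransduction kinase inaC (4.91), CG5653 (4.90), CG12605 (4.89) and the secreted ligand jeb (4.82). In that set unc-4 (-4.02), the homeobox gene lbl (-4.00) and Cpr65Ec (-3.85) joined the antennal disc side. Over the 4861 tested genes without overlap, 749 were higher in eye disc and 592 in antennal disc.

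Genes of eye formation and photoreceptor fate were higher in eye disc as groups. Of 10 retinal determination genes, 7 were higher in eye disc, 1 in antennal disc and 2 were not called, the same counts as when adjusted over the list alone (median log2 fold change 2.10, camera, Benjamini-Hochberg adjusted p = 0.00027, and adjusted p = 0.191 with an estimated correlation). Within this list dac, a nuclear cofactor of the network, was at 336 ± 15.9 against 49.6 ± 17.5 CPM, and eyg was the member higher in antennal disc (log2 fold change -1.05). Of 29 genes of ommatidial neurogenesis and photoreceptor fate, 25 were higher in eye disc and 4 were not called, and adjusted over the list alone 25 were higher in eye disc and 1 in antennal disc (median 1.58, camera adjusted p = 5.81e-13, and adjusted p = 0.179 with an estimated correlation). The receptor tyrosine kinase sev, needed for the R7 photoreceptor, was at 376 ± 22.1 against 19.1 ± 3.02 CPM, and the zinc finger gene scrt at 247 ± 26.8 against 17.1 ± 2.12 CPM. Of 15 tested phototransduction and late photoreceptor genes, 4 were higher in eye disc, 1 in antennal disc and 10 were not called, also when adjusted over the list alone (median 0.37, camera adjusted p = 0.104). inaC (42.0 ± 4.17 against 1.40 ± 0.497 CPM), rdgC (log2 fold change 2.89, and 3.62 without antennal disc replicate 2) and oc (0.90) were among the 4. ninaC was the member higher in antennal disc (-2.07), and its call held in 1 of the 6 fits that left out 1 library, the fit without eye disc replicate 3, at -3.05 there and at -2.22 to -1.76 where lost. Galphaq, not called, was at 83.2 ± 20.7 against 57.2 ± 6.03 CPM. The camera call of this list was gained without antennal disc replicate 2 (adjusted p = 0.026).

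Signalling genes of the differentiating eye also differed. Of 15 EGF receptor and Ras pathway genes, 9 were higher in eye disc, 2 in antennal disc and 4 were not called, also when adjusted over the list alone (median 0.51, camera, Benjamini-Hochberg adjusted p = 0.00402, and adjusted p = 0.35 with an estimated correlation). The members with the largest change were ru, aos, the protease rho (1.58) and the ETS factor pnt (1.30), and all but pnt are wholly covered by other genes. Among members that overlap no other gene the camera call was lost and turned toward antennal disc (adjusted p = 0.976). The 2 members higher in antennal disc, the receptor Egfr (-0.23) and its ligand vn (-0.34), mostly lost their calls with fewer libraries: Egfr was called in 1 of the 6 fits that left out 1 library, the fit without antennal disc replicate 2, and vn in none (edgeR quasi-likelihood test, highest adjusted p = 0.124 and 0.123). Of 14 Enhancer of split and Bearded complex genes, targets of Notch signalling, 7 were higher in eye disc and 7 were not called, and adjusted over the list alone 8 were higher in eye disc and 1 in antennal disc (median 0.63, camera adjusted p = 0.0167, and adjusted p = 0.648 with an estimated correlation). E(spl)mgamma-HLH was at 149 ± 27.8 against 22.4 ± 2.77 CPM, E(spl)mdelta-HLH at 106 ± 15.6 against 30.2 ± 1.44 CPM and Brd at 149 ± 22.7 against 44.4 ± 0.884 CPM. E(spl)mbeta-HLH, not called over all genes, was at 85.6 ± 15.4 against 112 ± 1.76 CPM. The call of this list was lost without eye disc replicate 1 (camera adjusted p = 0.0578).

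Genes of antennal and proximodistal fate were split between the tissues. Of 27 tested, 15 were higher in antennal disc, 9 in eye disc and 3 were not called, and adjusted over the list alone the counts were 15 and 10 (median -1.02, camera, Benjamini-Hochberg adjusted p = 0.0219, and adjusted p = 0.35 with an estimated correlation). Beside Dll, the zinc finger gene disco was at 7.97 ± 1.27 CPM in eye disc and 83.5 ± 7.96 CPM in antennal disc, disco-r at 27.1 ± 4.20 against 243 ± 16.2 CPM and btd at 2.70 ± 0.673 against 24.1 ± 3.55 CPM. The members higher in eye disc included dac, dan and danr, and dac is also in the retinal list. This call was lost with the replicate number as a block (camera adjusted p = 0.0542) and without antennal disc replicate 1 (adjusted p = 0.0506). All 4 Odd-skipped family genes, zinc finger factors of joints and the eye margin, were higher in antennal disc, also when adjusted over the list alone: odd (-1.63), drm (-1.36), sob (-1.24) and bowl (-0.58). Their median was -1.30 (camera adjusted p = 0.000372, and adjusted p = 0.258 with an estimated correlation).

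Morphogen and anteroposterior patterning genes were higher in antennal disc. Of 20 tested, 14 were higher there, 1 in eye disc and 5 were not called, and adjusted over the list alone 16 were higher in antennal disc and 1 in eye disc (median -0.89, camera, Benjamini-Hochberg adjusted p = 6.77e-08, and adjusted p = 0.179 with an estimated correlation). The Wnt ligand wg was at 29.1 ± 6.50 CPM in eye disc and 136 ± 7.63 CPM in antennal disc, and Wnt6 at 18.2 ± 1.89 against 94.4 ± 4.48 CPM. inv, a homeobox gene of posterior compartments, was at 18.5 ± 3.61 against 79.0 ± 6.44 CPM, and vg at 0.943 ± 0.457 against 5.44 ± 0.262 CPM. The member higher in eye disc, bi (0.55), was not called without antennal disc replicate 1 (edgeR quasi-likelihood test, adjusted p = 0.0582) or antennal disc replicate 2 (adjusted p = 0.075). Of 12 tested Hox and head gap genes, 4 were higher in antennal disc, 1 in eye disc and 7 were not called, and adjusted over the list alone the counts were 4 and 2 (median -0.35, camera adjusted p = 0.0793, and 0.0289 without eye disc replicate 2). The Hox gene Dfd was at 12.4 ± 3.34 against 78.9 ± 5.27 CPM and the head gap gene ems at 34.0 ± 3.89 against 80.1 ± 5.16 CPM. The Hox genes lab (10.1 ± 0.923 against 12.1 ± 1.15 CPM) and Scr (9.30 ± 10.2 against 21.1 ± 11.3 CPM) were not called. Of 17 dorsoventral eye patterning genes, 7 were higher in eye disc, 5 in antennal disc and 5 were not called, with 7 and 6 adjusted over the list alone. Their median was -0.13 and their mean 0.10, with camera toward antennal disc (adjusted p = 0.780). Among them the LIM homeobox gene Lim3 was at 23.0 ± 2.93 against 1.09 ± 0.218 CPM, pnr differed by 0.89 and the Notch ligand Ser by -0.81.

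**Figure D2:**
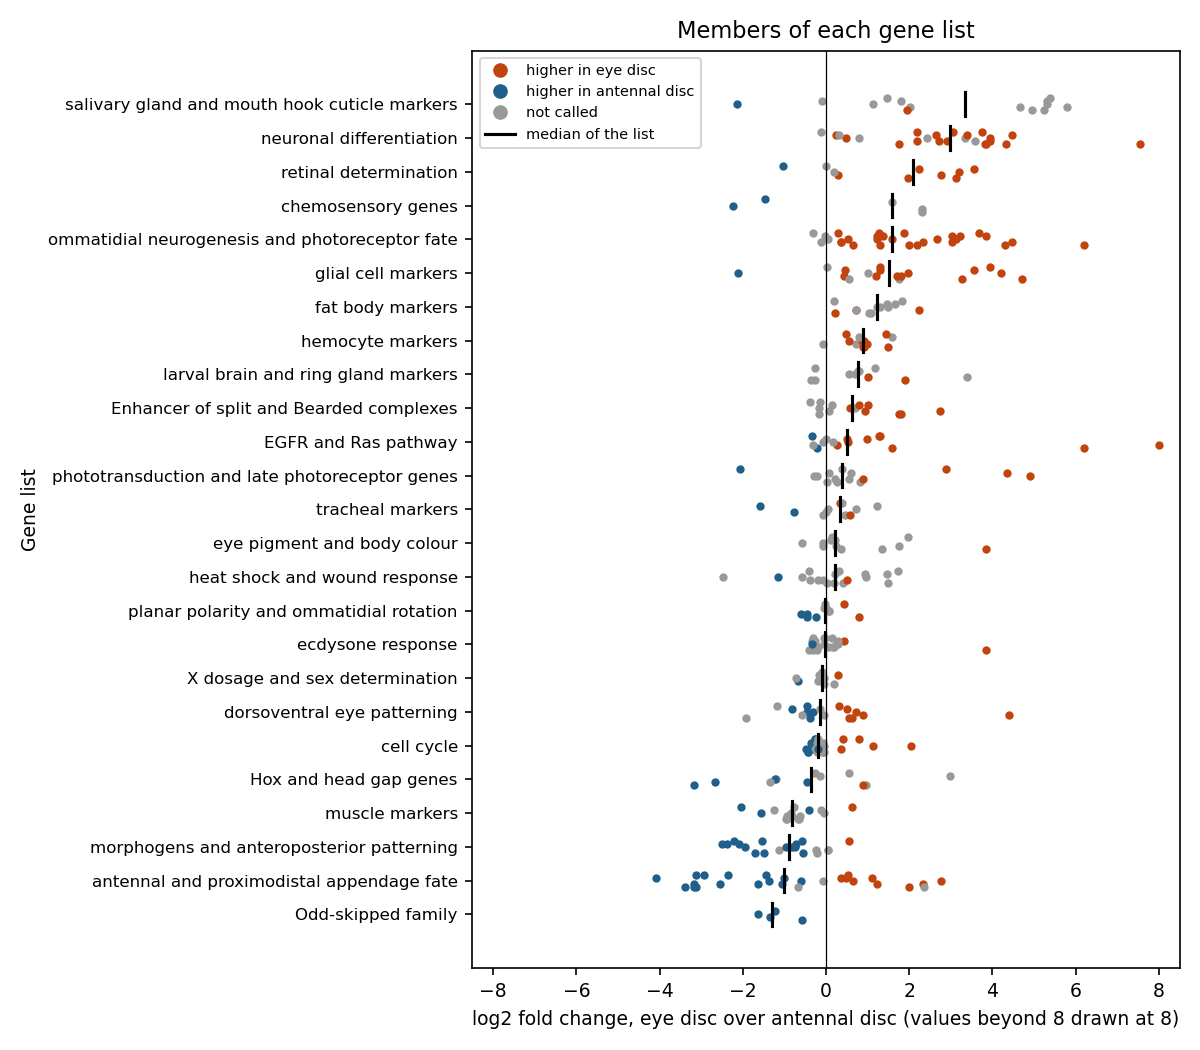
log2 fold change of each tested member of the 25 gene lists, eye disc over antennal disc, one point per gene coloured by its call and a black bar at the median of the list. Points beyond 8 are drawn at 8. The list of photoreceptor fate has 25 of 29 members higher in eye disc, and that of morphogens 14 of 20 higher in antennal disc.

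Markers of neurons, glia and hemocytes were higher in eye disc. Of 24 neuronal differentiation genes, 18 were higher in eye disc and 6 were not called, and 20 were higher when adjusted over the list alone (median 2.98, camera, Benjamini-Hochberg adjusted p = 6.72e-09, and adjusted p = 0.35 with an estimated correlation). The synaptic scaffold gene brp was at 143 ± 40.5 against 6.46 ± 1.32 CPM, Appl at 367 ± 75.1 against 18.2 ± 4.15 CPM and the sodium channel gene para at 19.0 ± 8.35 against 1.23 ± 0.372 CPM. The syntaxin gene Syx1A (37.3 ± 4.18 against 40.5 ± 4.41 CPM, wholly covered by other genes) and unc-13 (322 ± 55.0 against 259 ± 24.1 CPM) were not called, but unc-13 was with the replicate number as a block (edgeR quasi-likelihood test, adjusted p = 0.0279). Transcripts of 3 genes used by larval brain neurons, Gad1, VGlut and Ilp2, summed to 34.1 CPM in eye disc replicate 3 and to between 1.00 and 5.64 CPM in the other libraries, and 16 neuronal genes were called without that replicate. Of 18 tested glial markers, 13 were higher in eye disc, 1 in antennal disc and 4 were not called, with 14 and 1 adjusted over the list alone (median 1.51, camera adjusted p = 1.39e-05, and adjusted p = 0.178 with an estimated correlation). Beside repo, the log2 fold changes of alrm, moody, gcm2 and gcm were 4.71, 4.20, 3.95 and 3.55, and alrm and moody are wholly covered by other genes. Here alrm was at 5.50 without antennal disc replicate 2 and gcm at 4.17 without antennal disc replicate 1. The member higher in antennal disc was bnb (-2.10), and Gs2, at 199 ± 124 against 98.1 ± 20.8 CPM, was not called. Of 13 tested hemocyte markers, 9 were higher in eye disc and 4 were not called, also when adjusted over the list alone (median 0.89, camera adjusted p = 0.000121, and adjusted p = 0.178 with an estimated correlation). The prophenoloxidase genes PPO2 and PPO1 were at 368 ± 48.3 against 131 ± 3.38 CPM and at 292 ± 28.1 against 107 ± 11.0 CPM, PPO1 being wholly covered by another gene, and srp differed by 0.99. Hml (123 ± 45.7 against 74.6 ± 19.3 CPM) and NimC2 (78.4 ± 56.6 against 26.1 ± 10.7 CPM) were not called, but Hml was with the block (edgeR quasi-likelihood test, adjusted p = 0.00593).

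Transcripts of other larval tissues were uneven between libraries of the same group. In eye disc replicate 2, 7 genes of the salivary glue, Sgs3 and Sgs7 among them, summed to 102027 CPM, 9.08% of its estimated counts and 30.4% of its TPM, against 477 to 1514 CPM in the other 5 libraries. This library also held 26230 CPM of 6 larval serum and other fat body protein genes, against 3500 to 8740 CPM elsewhere, and 1870 CPM of 4 larval cuticle genes, against 95.3 to 497 CPM. Of 14 tested salivary gland and mouth hook cuticle markers, 1 was higher in eye disc, 1 in antennal disc and 12 were not called, with 0 and 1 adjusted over the list alone (median 3.34, camera, Benjamini-Hochberg adjusted p = 0.382, and 0.0391 without eye disc replicate 1). Sgs3 was at 26530 CPM in eye disc replicate 2 and at 124 to 315 CPM in the others. TwdlT, wholly covered by another gene, was the member higher in antennal disc (-2.13), and Lcp65Ag1, the member higher in eye disc (1.94), was called in 1 of the 6 fits that left out 1 library, the fit without eye disc replicate 1. With the replicate number as a block 2 of this list were higher in eye disc and 1 in antennal disc. Of 13 fat body markers, 3 were higher in eye disc and 10 were not called, with 2 and 0 adjusted over the list alone (median 1.21, camera adjusted p = 0.0229, and adjusted p = 0.537 with an estimated correlation). This call was lost without eye disc replicate 2 (camera adjusted p = 0.0579), without eye disc replicates 2 and 3 (0.817) and among genes without overlap (0.153). The yolk protein gene Yp2 (2.23), FASN1 (0.72) and Lpin (0.21) were the 3. FASN1 was not called without antennal disc replicate 1 or antennal disc replicate 2 (edgeR quasi-likelihood test, adjusted p = 0.0596 and 0.0635), and Lpin without any 1 of the 6 libraries, at 0.14 to 0.24, nor with the block (adjusted p = 0.0552). Lsp2 (4187 ± 4023 against 1191 ± 192 CPM) and Fbp1 (4514 ± 3246 against 1596 ± 600.1 CPM) were not called.

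**Figure D3:**
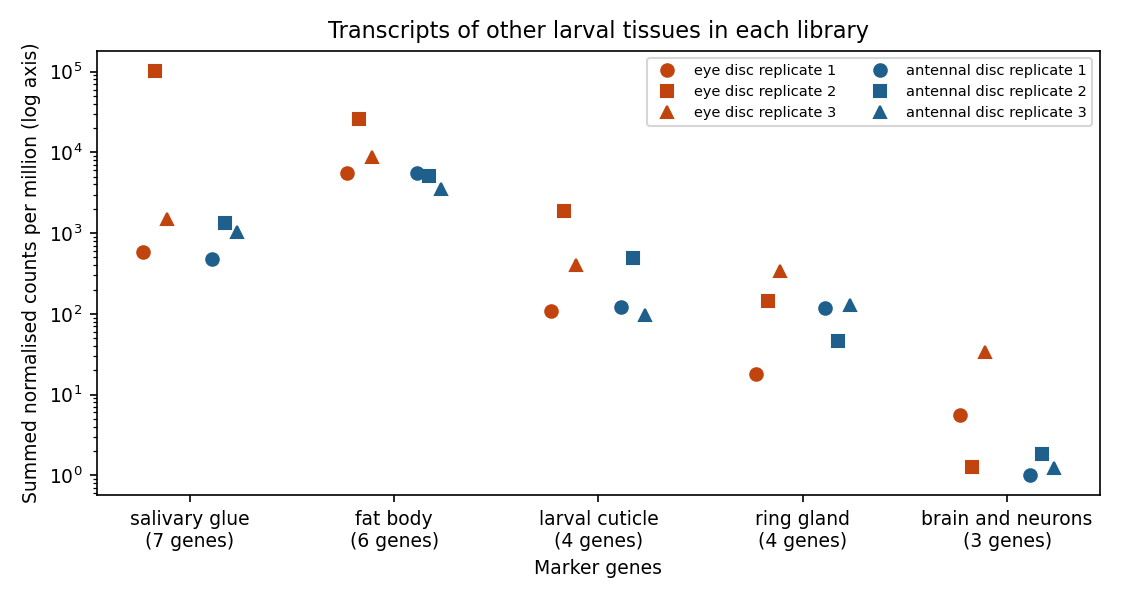
Summed normalised counts per-million (log axis) of marker genes of 5 other larval tissues, one point per library. Salivary glue genes reach 102027 in eye disc replicate 2 and lie at 477 to 1514 in the other libraries, and ring gland and brain genes are highest in eye disc replicate 3.

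Muscle markers as a list lay toward antennal disc, though few passed singly. Of 17, 3 were higher in antennal disc, 1 in eye disc and 13 were not called, also when adjusted over the list alone (median -0.82, camera, Benjamini-Hochberg adjusted p = 0.00533, and adjusted p = 0.537 with an estimated correlation). The titin-related gene bt was at 8.14 ± 1.22 against 24.1 ± 4.03 CPM, how differed by -0.42 and sls by 0.62. The myosin heavy chain Mhc, at 11.7 ± 6.08 against 48.0 ± 1.57 CPM (log2 fold change -2.04), was not called in 4 of the 6 fits that left out 1 library, those without eye disc replicate 3 or any 1 antennal disc replicate, at -2.22 to -2.02. Without eye disc replicate 2 the members higher in antennal disc were 6. Act57B (98.5 ± 54.0 against 191 ± 24.4 CPM) and Mlc2 (91.9 ± 54.1 against 162 ± 36.5 CPM) were not called. Of 11 tracheal markers, 2 were higher in each tissue and 7 were not called, also when adjusted over the list alone (median 0.34, camera adjusted p = 0.583). These were obst-A (0.57) and the chitin synthase kkv (0.34) in eye disc, and dysf (-1.58) and pio (-0.76) in antennal disc, pio being lost without antennal disc replicate 3 (edgeR quasi-likelihood test, adjusted p = 0.0532). Of 11 tested larval brain and ring gland markers, 2 were higher in eye disc and 9 were not called, with 0 adjusted over the list alone (median 0.77, camera adjusted p = 0.780). The neuroblast genes wor (1.9) and mira (1.01, wholly covered by other genes) were the called members, and each was called in 1 of the 6 fits that left out 1 library, the fit without eye disc replicate 2. Without eye disc replicate 2, 4 of 12 tested members were higher in eye disc and 0 in antennal disc. Without eye disc replicate 3 the counts were 0 and 1. With the replicate number as a block 1 of this list was higher in each tissue, and wor was not called (edgeR quasi-likelihood test, adjusted p = 0.0855). The ecdysone synthesis gene phtm was at 7.78, 71.6 and 173 CPM in eye disc replicates 1, 2 and 3 and was not called.

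Cell cycle genes were called in both directions. Of 28 tested cell cycle genes, 9 were higher in antennal disc, 5 in eye disc and 14 were not called, with 12 and 5 adjusted over the list alone. Their median was -0.18 (camera, Benjamini-Hochberg adjusted p = 0.0573), and the call was gained with the replicate number as a block (adjusted p = 0.0257), without eye disc replicate 3 (0.0344) and without antennal disc replicate 1 (0.0127). The mitotic phosphatase stg was at 346 ± 20 against 84.5 ± 12 CPM, while the cell cycle exit genes dap and fzr differed by 1.12 and 0.78. CycA was at 262 ± 21.3 against 291 ± 6.07 CPM and was not called. The members higher in antennal disc numbered 4 without eye disc replicate 2 and 6 without eye disc replicate 3. Of 20 tested ecdysone response genes, 2 were higher in eye disc, 1 in antennal disc and 17 were not called, also when adjusted over the list alone. With the replicate number as a block 2 were higher in eye disc and 4 in antennal disc. Their median was -0.03 and their mean 0.16, with camera toward antennal disc (adjusted p = 0.780). Eip93F was at 22.7 ± 9.71 against 1.57 ± 0.922 CPM. Eip75B (0.42) was not called without any 1 antennal disc replicate, nor br (-0.33, wholly covered by another gene) without antennal disc replicate 3 (edgeR quasi-likelihood test, highest adjusted p = 0.0785 and 0.0602).

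Of 11 planar polarity genes, 4 were higher in antennal disc, 2 in eye disc and 5 were not called, also when adjusted over the list alone (median -0.03, camera, Benjamini-Hochberg adjusted p = 0.449). The atypical cadherin stan differed by 0.79, and dachs and fj by -0.61 and -0.47. Of 5 tested chemosensory genes, 2 were higher in antennal disc and 3 were not called, with 2 in antennal disc and 1 in eye disc adjusted over the list alone. Their median was 1.59 and their mean 0.49, with camera toward antennal disc (adjusted p = 0.780). The odorant-binding protein gene Obp99a was at 106 ± 20.5 against 502 ± 96.4 CPM. The POU factor pdm3 differed by -1.48 and was just lost without antennal disc replicate 3 (edgeR quasi-likelihood test, adjusted p = 0.050). Of 18 tested heat shock and wound genes, 1 was higher in each tissue and 16 were not called, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.875), against 2 in eye disc and 4 in antennal disc with the replicate number as a block. GstD1 was at 465 ± 74.3 against 1036 ± 10.3 CPM, stv (0.50) was called in 2 of the 6 fits that left out 1 library, those without eye disc replicates 1 or 2, and Hsp27 (2966 ± 583 against 3888 ± 489 CPM) was not called, but was with the block (edgeR quasi-likelihood test, adjusted p = 0.00983). Of 9 dosage compensation and sex determination genes, 1 was higher in each tissue and 7 were not called, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.452), and 2 were higher in antennal disc with the block. These were dsx (-0.68) in antennal disc and tra (0.29) in eye disc, and tra was called in 1 of the 6 fits that left out 1 library, the fit without eye disc replicate 1, and not with the block (adjusted p = 0.0677). Of 12 tested eye pigment and body colour genes, the transporter st was higher in eye disc (3.84) and 11 were not called, also when adjusted over the list alone (median 0.22, camera adjusted p = 0.191). With a correlation estimated from the data, none of the 25 lists passed by camera (smallest adjusted p = 0.178), 5 passing at an unadjusted p under 0.05, against 12 with the preset correlation.

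The second comparison asked whether genomic regions tied to BAC clones held different numbers of active genes in the tissues. The mean number per region did not pass a test at any threshold of activity used, and its direction depended on the threshold. Single genes within the regions differed, at a share similar to that of all tested genes. Counting a gene as active above TPM 0, a region held 12.3 ± 0.341 active genes in eye disc and 12.5 ± 0.321 in antennal disc (SD, n = 3 libraries). The difference of -0.128 was smaller than the spread between replicates (exact two-sided permutation test, p = 0.8, where 3 against 3 cannot go below 0.1). A threshold of 1 CPM, here without TMM scaling, was chosen after the data were seen. With it the means were 9.87 ± 0.179 and 9.41 ± 0.0513, with all 3 eye disc libraries above all antennal disc libraries (exact permutation p = 0.1, the smallest possible). TPM is lowered for other genes in eye disc replicate 2, where glue genes hold 30.4% of it. Unscaled CPM is lowered there too, as glue genes hold 9.08% of the counts. Among called region genes the largest log2 fold change was that of CG15322 toward antennal disc (-4.35) and of CG12531 toward eye disc (4.57).

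The 39 regions, 24 of them on chromosome arm 3R, spanned 57.7 to 459 kb, with a median of 95.1 kb, and overlapped in part, so that 107 of their 453 genes lay in more than 1 region. Of 286 tested genes in the regions, 43 were higher in eye disc and 36 in antennal disc (edgeR quasi-likelihood test), 21 and 9 of them by at least 2-fold. Over all 9901 tested genes 1449 and 1161 were called, a similar share. By at least 2-fold these were 913 and 171, a split further toward eye disc than the 21 and 9 of the regions. That difference was not tested. A gene called by at least 2-fold lay in 24 regions, of which 7 held ss. Above TPM 1, a region held 9.53 ± 0.372 active genes in eye disc and 9.39 ± 0.129 in antennal disc (exact permutation test, p = 0.6). At this threshold all 3 eye disc libraries lay above all antennal disc libraries in 2 regions and below in 4, where chance gives 10% of the regions without ties, and above TPM 0 in none. The 2 regions were 3R 6642986 to 6746587 (10.3 ± 1.15 against 7.33 ± 0.577 genes) and 3R 11313137 to 11419660 (7 against 6 in every library). Of the 4, those on 3R start at 16280788, 16323955 and 16366694 and hold both ss and js, and that on X spans 20122256 to 20183650 and holds CG15322.

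Genes above TPM 1 in all libraries of 1 tissue and in none of the other numbered 5 for eye disc and 2 for antennal disc, and were named after their values were seen. In eye disc these were CG3257 (6.50 ± 3.88 against 0.812 ± 0.0956 TPM), pros, a determinant of R7 and cone cells (3.89 ± 3.71 against 0.490 ± 0.0774 TPM), CG12531 (2.78 ± 1.81 against 0.124 ± 0.0131 TPM), and the cuticle protein genes Ccp84Ad (2.99 ± 1.42 against 0.697 ± 0.232 TPM) and Ccp84Af (2.40 ± 1.47 TPM, and listed at 0 in antennal disc). Ccp84Af did not pass the count filter, so it was not tested between tissues. In antennal disc the genes were js (0.471 ± 0.230 against 2.34 ± 0.396 TPM) and CG15322 (0.135 ± 0.0556 against 3.13 ± 0.279 TPM). In the edgeR quasi-likelihood test the call of pros was lost without any 1 antennal disc replicate (highest adjusted p = 0.0952) and with the replicate number as a block (adjusted p = 0.064), its log2 fold change of 3.04 being 2.10 without eye disc replicate 3, that of Ccp84Ad without these or eye disc replicate 3 (highest adjusted p = 0.0802) and that of js without antennal disc replicate 3 (adjusted p = 0.0529). The gene ss, which 7 regions hold in whole or part, was at 0.936 ± 0.313 TPM in eye disc and 8.15 ± 0.718 TPM in antennal disc. In the regions around it Sulf1 (log2 fold change 0.41) and CG14883 (0.92) were higher in eye disc. Of the 453 genes, 235 were above TPM 1 in all libraries, 160 in none and 79 were listed at 0 in all.

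**Figure D4:**
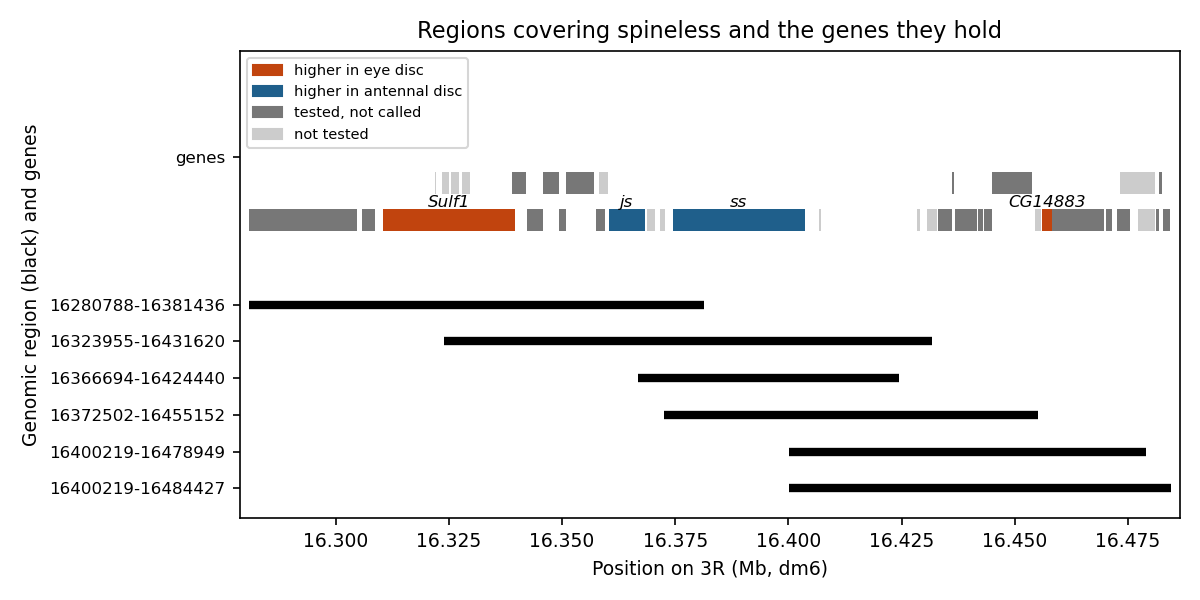
Position on chromosome arm 3R (Mb, dm6) of 6 regions that hold all or part of ss (black bars) and of the genes in them, coloured by their call between eye disc and antennal disc. js and ss were higher in antennal disc, Sulf1 and CG14883 higher in eye disc; the longest region holding ss, of 459 kb, is not drawn.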

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

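The fits to genes without overlap, to sums over overlapping genes, without eye disc replicates 2 and 3, and at 1 CPM were chosen after the data were seen. Counts stayed within 1.5 times their value under DESeq2 size factors, upper-quartile scaling, both other count filters, the DESeq2 Wald test, effective-length offsets and the replicate block, which called 12 lists too. Of the 2610 called genes, 2591 were called with DESeq2 size factors, 2567 with upper-quartile scaling, 2444 with the block and 917 with limma-trend on log2(TPM + 1). Under that last test 858 genes were higher in eye disc, 344 in antennal disc and 558 in eye disc by at least 2-fold. That fit also moved the median of all genes by -0.19. In eye disc replicate 2 glue genes hold 30.4% of the TPM, which lowers the TPM of all other genes there and widens the eye disc spread. How much of the lower counts and of the moved median this accounts for was not tested. Leaving out 1 library gave 919 to 1462 genes in eye disc and 520 to 1117 in antennal disc, and leaving out eye disc replicates 2 and 3 gave 569 in antennal disc, all with fewer samples. Among genes without overlap, a smaller set, 737 and 615 were called, 605 by at least 2-fold and 490 of these in eye disc. An adjusted p under 0.01 gave 847 and 428 genes. Tested against a 2-fold change 627 genes passed, 540 in eye disc and 87 in antennal disc, and a log2 fold change of at least 2 left 686, 76 of them in antennal disc. With an estimated correlation 0 of 25 lists passed by camera (limma), 5 at an unadjusted p under 0.05. The block ended the call of the antennal list and made that of the cell cycle list, ended 6 and made 3 calls of the genes followed singly and changed no other of these calls, and log2(TPM + 1) added the phototransduction, Hox and salivary gland lists. Without overlapping genes the EGF receptor and fat body lists lost their calls, and without eye disc replicate 2 the fat body list did.

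The difference in active genes per region turned to 0.137 above TPM 1, 0.0513 above TPM 10 and 0.462 above 1 CPM (exact permutation p = 0.6, 0.9 and 0.1, the smallest possible), and ranged from -0.316 to 0.0171 with 1 library left out. Its cause was not tested. A block by replicate number cannot move this difference of -0.128, and the permutation within the 3 pairs gave p = 1, where 0.25 is the smallest possible. The genes followed singly, nearly all of them named, numbered 162, 143 of them called: of 2523 values under 16 alternatives, 2316 kept direction and call, 180 lost the call, 19 gained it and 8 turned. Those 8 were Lpin at -0.00756 and phtm at -0.23 under limma-trend on TPM, roX1 at 0.0793, Sgs3 at -0.86, Sgs7 at -0.61 and phtm at -2.75 without eye disc replicates 2 and 3, and Sgs3 and phtm with 1 library left out, at -0.0663 to 5.87 and -0.42 to 1.23. Of these only Lpin was called, and the cause for it was not tested. Among the 28 uncalled genes left unnamed, 51 of 435 values turned. Transcript usage was not run. Depth limits the lowest genes: 3 counts are 0.192 CPM in eye disc replicate 2, the shallowest library.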

Other observations

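All tests in this part were chosen after the result was seen, those of gene families included.

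Gene families beyond the fixed lists also differed between the tissues. Families were taken as genes whose symbols share a stem, with at least 5 tested members, and of 141 such families 25 passed by camera (limma, Benjamini-Hochberg adjusted p under 0.05), 9 toward eye disc and 16 toward antennal disc. None passed with an estimated correlation (smallest adjusted p = 0.818). Of 18 tested dpr genes, immunoglobulin-domain receptors of neurons, 12 were higher in eye disc and 6 were not called (median log2 fold change 3.18, camera of limma, adjusted p = 6.77e-06), with dpr12 at 37.8 ± 5.58 against 2.06 ± 0.689 CPM (SD, n = 3). Their relatives in cell adhesion followed, with 6 of 11 beat genes, 6 of 8 side genes and 4 of 6 kek genes higher in eye disc, and 1 side gene higher in antennal disc. All 5 synaptotagmin genes and 6 of 7 Osiris genes, which encode proteins of cuticle-forming epithelia, were higher in eye disc, the Osiris median being 3.19 (camera of limma, adjusted p = 0.000547). Toward antennal disc most shifts were smaller: 15 of 21 Nup genes of the nuclear pore (median -0.24), 11 of 30 RNA polymerase genes (-0.18), 7 of 8 CCT chaperonin genes (-0.32), 6 of 8 Rrp exosome genes (-0.29) and 6 of 46 mitochondrial ribosomal mRpL genes (-0.17). The mRpL count was near the share of all tested genes, of which 1161 of 9901 were higher in antennal disc. Of 5 Wnt genes, 3 were higher in antennal disc (median -1.13). The medians had these signs under DESeq2 size factors, upper-quartile scaling and log2(TPM + 1) too, though the first 2 move all genes nearly alike. Relative to the median of all genes, log2(TPM + 1) brought that of dpr to 0.52, of Osiris genes to 1.59 and of Wnt genes to -0.50. Those of Nup and CCT genes were -0.27 and -0.35. The added 1 shrinks differences at low TPM, and its part in these values was not tested.

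A set of 9 genes, ru and SmD3 among them, had an estimated count that rounds to 0 in every library of 1 tissue and were called higher in the other. Of these 9, 100% lie wholly inside another gene's span, against 8% of tested genes (Fisher's exact test, p = 1.29e-10), in line with reads being moved between overlapping spans. Counts summed over each gene and its overlapping genes kept between -10.0 and 5.38 times the difference (median 0.848, with members going both ways), 4 of the 9 under 0.5 of it. A real absence of the transcript therefore cannot be told apart from shared reads over the set. Some sums keep the difference, as for ru (391 against 193 CPM), and others do not, as for SmD3 (log2 ratio of sums 0.12, toward eye disc). A sum also holds the overlapping genes' own differences, so it cannot decide for a gene that is a small share of it. In antennal disc CR43361 was at 5.76 CPM in a sum of 264 CPM.

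Salivary glue transcripts made up 9.08% of the counts of eye disc replicate 2. Each of 7 glue genes was at least 60.2 times the median of the other 5 libraries there, and Sgs1 146 times, which is consistent with salivary gland RNA carried into this library. A wrong tissue label is argued against by the genes that the other 5 libraries alone call by at least 2-fold: on a scale from antennal disc (0) to the other eye disc libraries (1), this library lay at a median of 0.806 over 935 genes higher in eye disc (lower quartile 0.616) and 0.853 over 207 higher in antennal disc (0.573). The carried-over tissue stays a hypothesis, and no biological explanation was tested, since the labels give none within a tissue.

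Ecdysone response genes deviated together in the libraries of replicate 1 of both tissues, with a correlation of 0.882 across 20 genes, 17 of them deviating the same way. Larval timing shared by libraries of 1 number might give this, but the correlation lies at percentile 90.0 of 10000 random lists matched on level (median 0.470, 95th percentile 0.930), so that it cannot be told apart from the deviation that all genes share. Handling stress stays open as well: Hsp70 and Hsp68 genes of replicate 1 deviated by a median of 0.0581 in antennal disc and -1.11 in eye disc (log2, 4 genes), all 4 below the mean in eye disc and 2 above it in antennal disc, so that only 1 library speaks against it. The correlations for replicates 2 and 3 were 0.677 and 0.387.

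In eye disc replicate 3, 4 ring gland genes summed to 342 CPM, against 18.0 to 145 CPM in the other libraries. Hsp70 and Hsp68 genes summed to 211 CPM there, against 7.86 to 73.3 CPM. Genes at least 2-fold higher in antennal disc were at a median of 1.10 of the other eye disc libraries in eye disc replicate 2 and 0.859 in replicate 3, and genes at least 2-fold higher in eye disc at 0.8 and 1.24. Of the 10 splits of the 6 samples into 3 and 3, only 1, the real one, called as many as 2610 genes by the edgeR quasi-likelihood test, and the highest of the others called 0, but 10 splits are too few for a share under 0.05. Of the splits that part all 3 pairs of equal number, the other 3 called 0 too. Each split but the real one puts libraries of both tissues in each group. Tissue differences then add to the spread within groups and lower the calls. The counts of 0 therefore cannot show how many calls would arise without a tissue difference.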
